A study of Mus musculus with 8 samples.

How the data were processed

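Gene expression was measured in liver tissue of 8 male C57BL6/N mice with Affymetrix Mouse Genome 430 2.0 arrays, a 3'-biased oligonucleotide array on which a group of short probes (a probe set) reports the signal of 1 transcript. Total RNA was reverse transcribed from an oligo-dT primer, labelled with biotin and hybridised with 1 array per mouse, per the labels' protocols. The deposited values are log2 signals, 1 per probe set and array. The submitters' processing notes name RMA, which corrects background, equalises the distributions of the arrays and summarises the probes of a probe set, and the R package oligo, version 1.52.0. Options, filters and the annotation used by the authors are not given in the sources used here. The table held 45101 probe sets with 0 missing values, the array medians lay between 5.66 and 5.72, and the highest value was 15.1. These log2 values are relative and depend on each probe set's own probes, so brightness was compared between probe sets as a rough guide and no more, to choose 1 probe set per gene, to choose the members named for lists without calls and to set the level taken as close to background and the filters on dim genes. Scanner images and probe-level values were not analysed here, so saturation of the brightest probe sets could not be checked. The number of arrays limits the precision.

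Groups were taken from the sample titles: 3 controls and 5 LPS mice. The titles carry replicate numbers, and each array came from a separate mouse, so no pairing is stated. All 8 columns of the table belong to a labelled sample. Of the probe sets, 64 control probe sets of the manufacturer were left out and 45037 remained. The platform annotation gave 1 gene symbol to 34945 of these, several to 932 and none to 9160. Of the probe sets with 1 symbol, 34741 had a gene identifier found in the RefSeq gene table of assembly GRCm38.p6, which was used only for names. The other 204 kept the symbol of the array annotation. Probe sets with several symbols or none were not named. No genomic coordinates are printed, because the genome build behind the probe sets is not given in the sources used here. For each of the 18193 named genes the probe set with the highest mean over the 8 arrays was used.

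The comparison of LPS with control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on the log2 values, with no filter on dim genes and no covariate. P-values were adjusted over all genes by the Benjamini-Hochberg method and called at an adjusted p below 0.05. Differences are LPS minus control in log2 units, with the moderated standard error (SE) of limma. Group means are given with the standard deviation (SD) over mice. Fixed lists of genes, 49 in number with at least 5 measured members each, were tested with limma's camera, a test of whether a list's genes rank higher or lower than all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Of 912 planned list entries, 809 had a measured gene. The list test was repeated with the correlation estimated from the 8 arrays and with limma's fry, which asks whether a list's genes move on balance in 1 direction without comparison with other genes.

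The design, the gene lists, the rule for naming genes and 22 alternative settings were fixed before the data were examined, and 1 setting (the beta-actin signal ratio as a covariate) was added afterwards. The genes named are the 12 with the largest positive and the 12 with the largest negative difference among called genes whose groups did not overlap, up to 4 called members of each list by size of difference or the 2 brightest members where none was called, and a set of fixed genes (Saa1, Alb, Tnf, Il1b, Il6, Nos2, Cd14, Tlr4, Cyp7a1, Cyp3a11, Cyp2e1, Hnf4a, Ppara, Pck1). This gave 137 genes, of which 101 were called. Of all 137, called or not, 55 had several probe sets, and 19 had at least 1 probe set that pointed the other way, but no such probe set passed the limma test. Any other gene is said to have been chosen after its values were seen. The alternatives covered the choice of probe set, filters on dim genes, variance models, array weights, the scaling of the arrays, the replicate number as a block, the list tests, a stricter threshold and each array left out in turn.

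The gene and list tests were tested on simulated data. In 20 simulations of 5 LPS against 3 control arrays, all 18193 genes were drawn from their means and SDs with independent errors. There 55.2% of genes changed by 0.5 log2 units were called, 94.9% of those changed by 1, 99.2% of those changed by 2 and 99.9% of those changed by 3. Of unchanged genes, 0.05% were called. A list of 25 genes shifted by 0.5 was called in 20 of 20 simulations, and 1 of 180 unshifted lists was called. Errors of real arrays are correlated between genes, so these rates do not carry over to the list tests on the real arrays. The changed genes were drawn at random, with 1 spread for both groups and no outlying mouse. The rates for genes therefore do not carry over to genes that varied more among the LPS mice. Cyp3a11, for example, differed by -1.05 with an SD of 0.61 among LPS mice and did not pass (limma adjusted p = 0.0609). Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and plots.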

Results

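Liver gene expression was compared between 5 male C57BL6/N mice, aged 8 to 10 weeks, that had received an intraperitoneal injection of lipopolysaccharide (LPS) at 750 µg per kg body weight and 3 control mice injected with phosphate-buffered saline. LPS is a component of the outer membrane of Gram-negative bacteria that is sensed through Toll-like receptor 4 and is used to provoke systemic inflammation. Livers of the LPS mice were taken 24 hours after the injection. The comparison asks which liver transcripts differed between the groups at that time.

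In LPS livers 20 of 25 acute phase protein genes, the metallothionein gene Mt2 and the chemokine gene Cxcl9 rose, while 8 of 28 phase II enzymes of drug metabolism, 8 of 27 genes of oxidative phosphorylation and 3 of 20 genes of lipid synthesis fell. These 4 lists shifted with a preset correlation between genes, but not with an estimated correlation (adjusted p = 0.255, 0.265, 0.255 and 0.289). Saa3, which encodes a serum amyloid A protein of the acute phase, rose from 7.39 ± 0.12 (SD, n = 3) in controls to 14.07 ± 0.42 (SD, n = 5), a difference of 6.67 with an SE of 0.20 (102-fold, adjusted p = 1.1e-08). Lcn2, encoding the iron-scavenging protein lipocalin 2, rose by 6.52 with an SE of 0.64 (91.7-fold, adjusted p = 0.00173), to 13.54 ± 1.04 (SD, n = 5). Me1, the NADPH-producing malic enzyme of the cytosol, fell from 10.80 ± 0.64 (SD, n = 3) to 8.70 ± 0.88 (SD, n = 5), or 4.30-fold (adjusted p = 0.0323). Of 18193 genes, 271 were higher and 250 lower in LPS, among them 81 at least 2-fold higher and 28 at least 2-fold lower. In the unadjusted limma test 3438 genes had a p below 0.05, and in 12.9% of genes the groups did not overlap, where chance gives 3.57%.

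These counts changed with each array left out. Without control replicate 1, 11 genes were higher and 2 lower. They were 30 and 7 without control replicate 2, 38 and 28 without control replicate 3, 50 and 25 without LPS replicate 1, and 67 and 31 without LPS replicate 2. They were 116 and 84 without LPS replicate 3, and 67 and 45 without LPS replicate 4. Without LPS replicate 5 they were 928 and 753, including all 271 and all 250 genes called with it. Among the 101 called genes named here, the 8 that passed with any single array left out were Saa3, Lcn2, Orm2, Saa2, Cxcl9, Ccl5, Marco and Igfbp2. Single controls moved several folds by over 1.5 times. Without control replicate 2 the log2 difference was 7.34 for Lcn2, 6.11 for Orm2, 5.54 for Saa2 and 3.03 for Saa1. Without control replicate 3 it was 5.88 for Lcn2, 3.98 for Saa2, 1.43 for Saa1, 4.59 for Mt2 and 4.03 for Mt1, and without LPS replicate 5 it was 3.42 for S100a9.

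The other genes with the largest increase included the acute phase genes Orm2 (44.8-fold) and Saa2 (26.6-fold) and Cxcl9 (23.4-fold), a chemokine for T cells. The metallothioneins Mt2 (14.1-fold) and Mt1 (10.1-fold), which bind zinc and copper, followed, and Serpina3n rose 8.05-fold. The signal of the scavenger receptor gene Marco rose by 3.15, that of the myeloid gene S100a9 by 2.82, that of Acnat2 by 2.43 and that of the ubiquitin-like gene Ubd by 2.42 log2 units. Of the called genes named here, 16 (these 4 included) had a group mean below 6.48, the 95th percentile of the mean signals of 75 sensory receptor genes, and 6 of them had both means below it. Signals there are close to background, so differences in log2 signal and no folds are given for them. Adjusted p-values of these genes with the largest increase lay between 0.00173 and 0.0347, and all 5 LPS mice lay above all 3 controls in each. Passing and this separation were the rule for choosing them and are no further support.

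Among genes whose groups did not overlap, the signal of Mme, encoding the peptidase neprilysin, fell by 2.29 log2 units (adjusted p = 0.0289), to a level close to background (4.32). Clec4f, a lectin of Kupffer cells, the resident macrophages of the liver, fell 3.91-fold (adjusted p = 0.029). Klf10 fell by 1.96, the fatty acid elongase gene Elovl3 by 1.86, the carboxylesterase gene Ces1e by 1.71 and the organic anion transporter gene Slco1a1 by 1.62 log2 units. The glutathione transferase gene Gsta4 fell by 1.59, Igfbp2 by 1.48, Ugt2b1 by 1.41, the major urinary protein gene Mup10 by 1.39 and Trib3 by 1.36. Adjusted p-values of these 12 genes, Me1 included, lay between 0.00276 and 0.0395, and all 5 LPS mice lay below all 3 controls, as the rule for choosing them required. With adjustment over every probe set, 1 of 2 probe sets passed for Mme, Me1, Slco1a1 and Mt1, and the only probe set of Ces1e did not pass. Further called genes named below had no passing probe set there. They were Abcb11, Acot1, Asl, Casp4, Ccl7, Cd5l, Cela1, Chil3, Cldn2, Cps1, Ctss, Cybb, Cyp1a2, Cyp27a1 and Cyp2f2. The same held for Eci1, Ehhadh, Elovl5, Fcna, Gnmt, Ireb2, Mlxipl, Ndufb5, Nfkbiz, Oat, Pdia4, Ppp1r3b, Sdf2l1, Slc37a4 and Sqle. With the mean of all probe sets of a gene, the difference was -1.17 for Mme, 2.26 for Marco, 2.22 for Mt1, 0.58 for Ddit3, 0.33 for Nfkbiz, 0.52 for Tfrc, -0.65 for Reln and -0.13 for Ighm. Of the 101 named calls 55 were kept in that setting, and those of Ddit3, Nfkbiz, Tfrc and Ighm were lost (adjusted p = 0.113, 0.299, 0.0619 and 0.299). Without probe sets that can match several transcripts, the difference was 1.12 for Mt1 and -0.03 for Ighm, and neither passed (adjusted p = 0.065 and 0.881). Over all alternatives the adjusted p lay between 2.61e-05 and 0.136 for Ddit3, 0.000555 and 0.299 for Nfkbiz, 4.15e-05 and 0.134 for Tfrc, 0.000633 and 0.881 for Ighm, and 0.000219 and 0.0945 for Mt1.

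**Figure D1:**
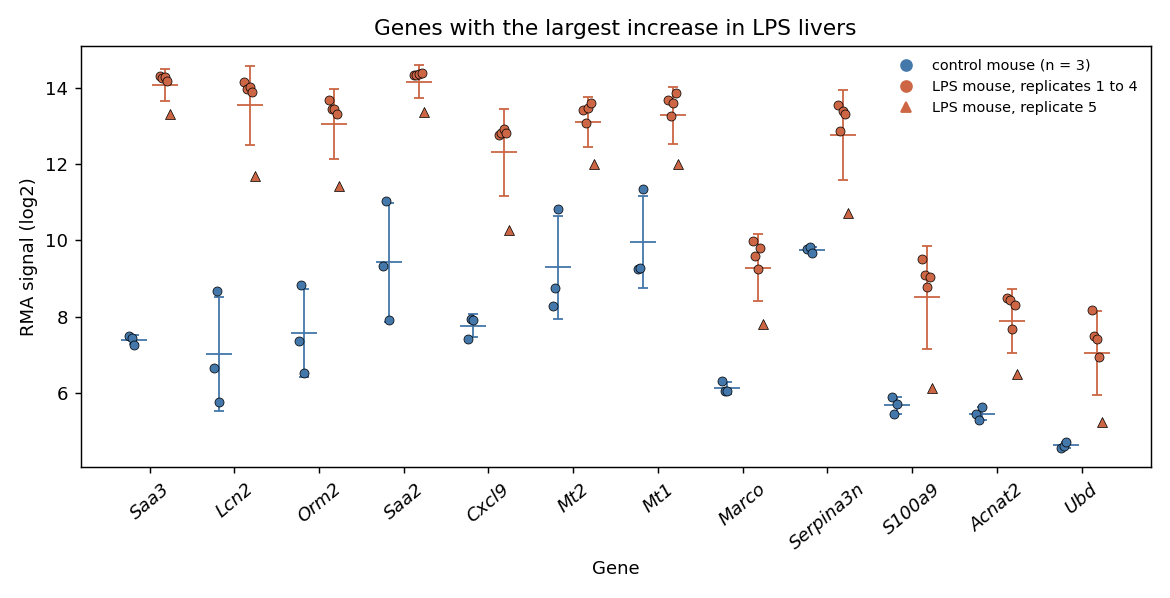
RMA signal (log2) of the 12 genes with the largest increase among called genes whose groups did not overlap. Each mouse has 1 circle, or a triangle for LPS replicate 5, with horizontal marks for group means and bars for the SD (3 control and 5 LPS mice). For Saa3, LPS replicate 5 lay at 13.3 and the other LPS mice between 14.2 and 14.3, against at most 7.48 in controls.

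**Figure D2:**
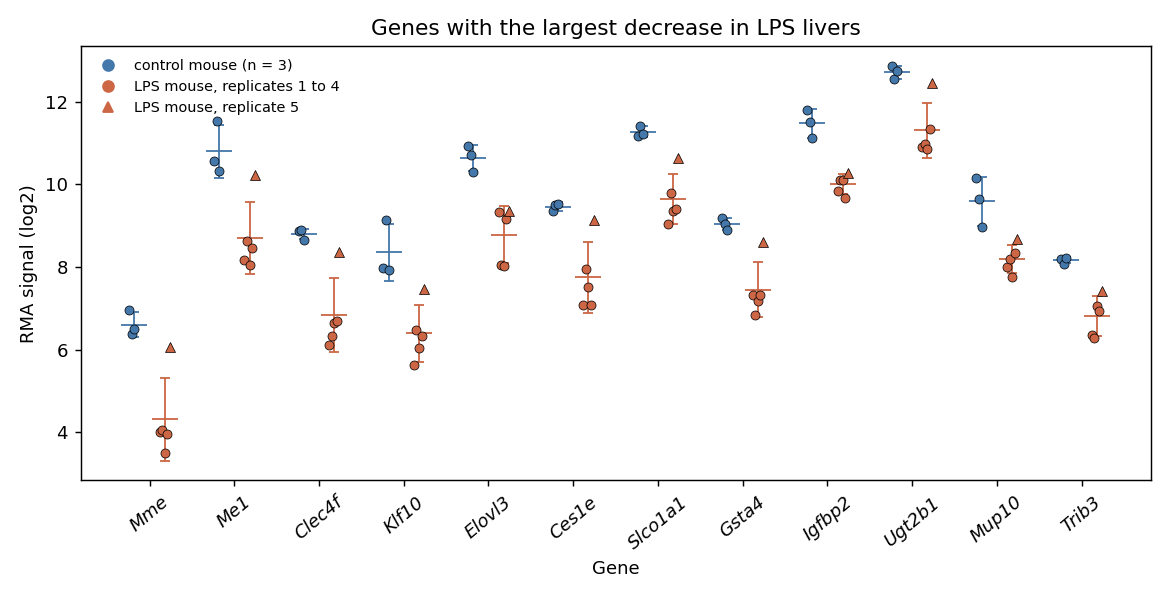
RMA signal (log2) of the 12 genes with the largest decrease among called genes whose groups did not overlap. Each mouse has 1 circle, or a triangle for LPS replicate 5, with horizontal marks for group means and bars for the SD (3 control and 5 LPS mice). For Mme, LPS replicate 5 lay at 6.07, close to the lowest control at 6.37, and the other LPS mice lay at 4.04 or lower.

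LPS replicate 5 lay nearer to the controls than the other LPS mice did. On the first principal component, which held 49.9% of the variance, the controls lay between -22.6 and -20.8, LPS replicates 1 to 4 between 16.3 and 23.9, and LPS replicate 5 at -9.85. The median SD per gene was 0.142 among LPS mice (0.1355 without LPS replicate 5) and 0.105 among controls. Controls differed too: control replicate 2 had the highest Lcn2 signal of the 3 (8.67, against 5.75 and 6.64), and Saa1 ranged from 10.42 to 13.62 among controls. The 3' to 5' signal difference of beta-actin, a measure of RNA quality, was 0.169 log2 units higher in LPS (exact permutation test, two-sided p = 0.536), and that of Gapdh 0.147 higher (exact p = 0.196). LPS replicate 3 had the highest value of all arrays for both, at 2.626 against 1.656 to 2.12 for beta-actin and at 0.752 against 0.281 to 0.578 for Gapdh. It also lay farthest from 0 on the second component, at 24.3.

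**Figure D3:**
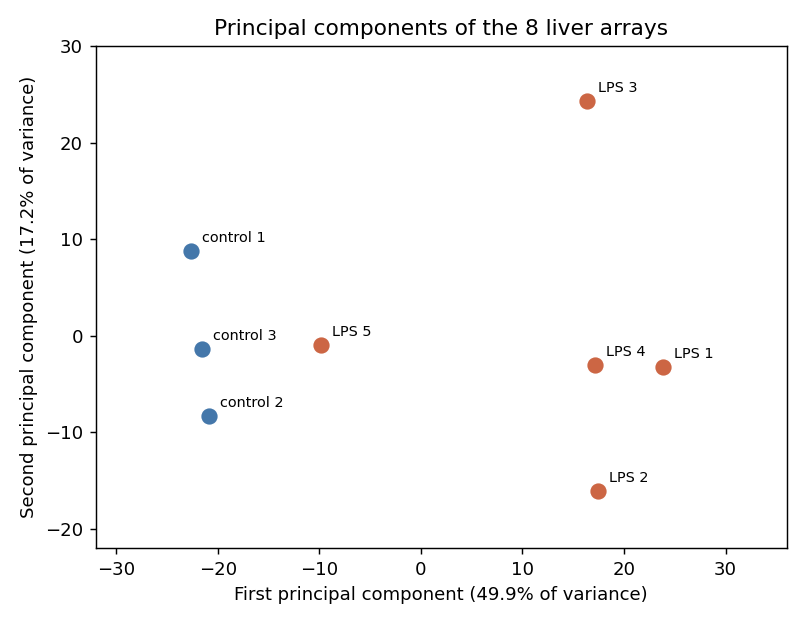
First and second principal components of the gene signals, with 1 point per mouse and the share of variance on each axis. LPS replicate 5, at -9.85 on the first component, lies between the controls (-22.6 to -20.8) and the other LPS mice (16.3 to 23.9), and the second component holds 17.2% of the variance.

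Acute phase genes, which encode plasma proteins secreted by hepatocytes in inflammation, had the largest median difference of all lists, at 1.27. Of 25 measured members, 20 rose, 0 fell and 5 did not pass (22 higher when adjusted over the list alone). The list shifted up (camera adjusted p = 1.18e-29, and adjusted p = 0.255 with an estimated correlation). Saa1 rose 4.99-fold (adjusted p = 0.0392), but passed in only 12 of 19 alternatives, with adjusted p between 0.0115 and 0.145. Other named calls passed in still fewer. Among them were Me1 and Gbp6 (8 of 19 each, highest limma adjusted p = 0.15 and 0.162) and S100a9 (9 of 19, highest 0.149). Of 16 carrier proteins that often fall in inflammation, 0 passed in limma (0 when adjusted over the list alone, 1 higher and 3 lower at an unadjusted p below 0.05), and the list was not shifted (adjusted p = 0.296). Albumin (Alb) differed by -0.10 (SE 0.07, adjusted p = 0.495) and transthyretin (Ttr) by -0.06, at signals near the top of the array's range.

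In the complement list Cfb (1.75-fold), C4bp (1.66-fold) and Serping1 (1.48-fold) rose among 19 members (8 higher and 2 lower when adjusted over the list alone). The list shifted up (adjusted p = 0.000174, and adjusted p = 0.255 with an estimated correlation), with a median of 0.16. Centring the arrays on reference genes lowered every gene by the same amount, mostly because the reference gene Tfrc rose in LPS. This put the complement median at -0.02, but relative to all genes it was 0.18 in both cases and the list was called in both. Coagulation genes gave 0 calls in limma among 18 members (0 when adjusted over the list alone, 4 higher and 1 lower at an unadjusted p below 0.05). Plg differed by 0.05 and Serpinc1 by -0.11, and that list was not shifted (adjusted p = 0.163).

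Of 16 interferon-gamma-inducible genes, 6 rose and 0 fell (9 higher when adjusted over the list alone), among them the GTPase genes Gbp6 (2.96-fold), Igtp (2.55-fold) and Irgm1 (1.95-fold). That list shifted up (camera adjusted p = 2.82e-09, and adjusted p = 0.255 with an estimated correlation). In the MHC class I list 4 of 12 rose (9 when adjusted over the list alone), with the peptide-loading gene Tapbp at 2.20-fold, the immunoproteasome gene Psmb8 at 2.03-fold, H2-D1 at 1.82-fold and H2-K1 at 1.39-fold. It shifted up too (camera adjusted p = 2.91e-09, and adjusted p = 0.255 with an estimated correlation). Among 25 type I interferon-stimulated genes only Irf7 passed (2.12-fold, adjusted p = 0.029), while 12 were higher when adjusted over the list alone. With a median of 0.31 this list shifted up (camera adjusted p = 2.91e-09, and adjusted p = 0.255 with an estimated correlation). MHC class II genes went both ways, with Ctss 1.45-fold higher and H2-Aa 1.66-fold lower among 9 members (1 higher and 1 lower when adjusted over the list alone), and the list was not shifted (adjusted p = 0.296).

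Of 30 cytokine and chemokine genes, 5 rose and 0 fell (11 higher when adjusted over the list alone), among them Cxcl9, Ccl6 (by 1.32 log2 units), Ccl5 (2.33-fold) and Ccl7 (by 0.99 log2 units). Together these genes shifted up (camera adjusted p = 1.54e-07, and adjusted p = 0.255 with an estimated correlation). Tnf and Il1b, early cytokines of the LPS response, did not pass, at 0.40 (SE 0.10, adjusted p = 0.056) and 0.44 (SE 0.17, adjusted p = 0.188). They passed without LPS replicate 5 (adjusted p = 0.033 and 0.00953), and over all alternatives their adjusted p lay between 0.0253 and 0.22 for Tnf and between 0.00953 and 0.42 for Il1b. Il6 differed by 0.11 (SE 0.08) at a signal near background (3.07 in LPS), and Nos2 by 0.13 (SE 0.17, adjusted p = 0.74).

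The LPS receptor gene Tlr4 differed by -0.22 (adjusted p = 0.196) and its co-receptor gene Cd14 by 0.77 (adjusted p = 0.149). Cd14 passed without LPS replicate 5 (adjusted p = 0.0447, with a range from 0.0303 to 0.34 over the alternatives). Control and LPS means lay below the level of 6.48 for Tnf (5.83 and 6.23), Nos2 (5.76 and 5.89) and Tlr4 (4.96 and 4.74), as did the control means of Il1b (6.38) and Cd14 (6.24), so that missing calls say little about these genes. Of 20 genes of the Toll-like receptor and NF-kB pathway, Nfkbiz and Tnfaip3, feedback regulators of NF-kB, rose by 0.94 and 0.71 log2 units (2 when adjusted over the list alone), Nfkbiz not with the mean of probe sets. That list shifted up (adjusted p = 0.0291, and adjusted p = 0.419 with an estimated correlation), with a median of 0.16, or -0.01 with reference centring, which was 0.18 relative to all genes in both cases, with the list called in both. For IL-6 and STAT3 signalling 0 of 15 passed in limma (2 higher when adjusted over the list alone, 4 higher and 0 lower at an unadjusted p below 0.05), with Stat3 at 0.28 and Cebpb at 0.01. Stat3 passed in 2 of 19 alternatives (limma adjusted p from 0.0393 to 0.449). The list still shifted up (adjusted p = 0.0146, and adjusted p = 0.419 with an estimated correlation), with a median of 0.12, or -0.06 with reference centring, which was 0.14 relative to all genes in both cases, with the list called in both.

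Of 14 monocyte and macrophage markers, 5 rose and 0 fell (9 higher when adjusted over the list alone), with Lgals3 at 1.62 and Chil3 at 1.55 log2 units, S100a6, and Plac8 at 2.78-fold. The list shifted up (camera adjusted p = 2.91e-09, and adjusted p = 0.255 with an estimated correlation). Among 13 Kupffer cell markers, Marco and Cd5l (1.37-fold) rose, and Clec4f and Fcna (1.63-fold) fell (3 higher and 4 lower when adjusted over the list alone), with no shift of the list (adjusted p = 0.563). S100a9 alone passed among 13 neutrophil markers (2 when adjusted over the list alone). Their median was -0.02, their mean 0.48 and the direction of the test up, without a shift (adjusted p = 0.146). The neutrophil list was called in 5 of 19 alternatives (camera adjusted p from 0.0188 to 0.428).

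The granzyme gene Gzma rose from 4.61 to 5.61, both close to background, as the only call among 14 T and NK cell markers (1 when adjusted over the list alone), a list with a median of -0.09, a mean of 0.04 and no shift (adjusted p = 0.988). The immunoglobulin heavy chain gene Ighm fell 1.80-fold as the only call among 9 B and plasma cell markers (1 when adjusted over the list alone), a call that other choices of its probe sets ended. That list shifted down (adjusted p = 0.00623, and adjusted p = 0.255 with an estimated correlation). Among 7 genes of the phagocyte oxidase and nitric oxide, the oxidase gene Cybb rose 1.89-fold, and Gch1, which serves the cofactor synthesis of nitric oxide synthases, fell 2.06-fold (4 higher and 1 lower when adjusted over the list alone). The list shifted up (adjusted p = 0.00623, and adjusted p = 0.255 with an estimated correlation).

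Of 28 phase II conjugation enzymes, 8 fell and 0 rose (17 lower when adjusted over the list alone), among them Gsta4, Ugt2b1 (2.65-fold), Gstm3 (2.39-fold) and Gstm6 (1.93-fold). Gsta2, chosen after its value was seen, had the largest difference of the list (-1.88, SE 0.48), but did not pass over all genes (adjusted p = 0.0591, and 0.00573 over the list alone). The list shifted down (camera adjusted p = 1.84e-09, and adjusted p = 0.265 with an estimated correlation). Of 32 phase I enzymes, Cyp1a2 (2.04-fold), Cyp2c55 (1.97-fold) and Cyp2f2 (1.69-fold) were among 4 that fell, and Cyp3a13 rose 1.81-fold (13 lower and 3 higher when adjusted over the list alone). That list shifted down (adjusted p = 0.0131, and adjusted p = 0.419 with an estimated correlation), but not with reference centring (adjusted p = 0.103, with a range from 0.000259 to 0.111 over the alternatives). There the median was -0.37 instead of -0.20, or -0.18 relative to all genes in both cases, and 11 members were called lower. Cyp3a11, a major drug-metabolising enzyme, differed by -1.05 (SE 0.27, adjusted p = 0.0609). It passed without LPS replicate 5 (adjusted p = 0.000119, with a range from there to 0.207), and Cyp2e1 differed by -0.07 (adjusted p = 0.667).

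Among 18 hepatobiliary transporters, Slco1a1, Abcg2 (1.60-fold) and the bile salt export pump gene Abcb11 (1.48-fold) fell (8 lower and 1 higher when adjusted over the list alone). The list shifted down (camera adjusted p = 8.37e-05, and adjusted p = 0.255 with an estimated correlation). In bile acid synthesis, Cyp8b1 (1.75-fold) and Cyp27a1 (1.57-fold) fell among 17 members (4 lower and 1 higher when adjusted over the list alone), without a shift of the list (adjusted p = 0.203). Cyp7a1, the rate-limiting enzyme of the classical pathway, differed by -0.04 with an SE of 0.39 (adjusted p = 0.971).

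Of 27 genes of oxidative phosphorylation, 8 fell and 0 rose (20 lower when adjusted over the list alone), by small amounts. Sdhb fell by 0.59, Cyc1 by 0.49, Ndufb5 by 0.46 and Atp5c1 by 0.46 log2 units. The list shifted down (camera adjusted p = 7.28e-13, and adjusted p = 0.255 with an estimated correlation). In fatty acid and triglyceride synthesis Me1, Elovl5 (2.05-fold) and Mlxipl (1.44-fold), the gene of the glucose-sensing factor ChREBP, fell among 20 members (10 lower when adjusted over the list alone). This list shifted down as well (camera adjusted p = 9.30e-08, and adjusted p = 0.289 with an estimated correlation). In fatty acid oxidation Acot1 (-1.51 log2 units), Ehhadh (2.23-fold) and Eci1 (1.31-fold) fell among 25 members (4 lower when adjusted over the list alone), without a shift of the list (adjusted p = 0.0826). The list of fatty acid oxidation genes was called in 5 of 19 alternatives (camera adjusted p from 0.00885 to 0.416). Ppara, a regulator of these genes, differed by -0.50 (adjusted p = 0.124) and passed without LPS replicate 5 (adjusted p = 0.0036, with a range from there to 0.356). Sqle, an enzyme of cholesterol synthesis, rose 1.59-fold as the only call among 18 (3 higher and 2 lower when adjusted over the list alone), in a list that shifted up (adjusted p = 0.00843, and adjusted p = 0.493 with an estimated correlation).

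In glucose metabolism the glycogen synthase gene Gys2 (2.21-fold) and the glucose-6-phosphate transporter gene Slc37a4 (1.56-fold) fell and Ppp1r3b rose (2.42-fold) among 14 genes (7 lower and 2 higher when adjusted over the list alone). Pck1 differed by -0.01 (SE 0.27). Of 28 genes of the urea cycle and amino acid catabolism, 5 fell and 0 rose (12 lower and 2 higher when adjusted over the list alone), with Oat at 2.17-fold, Asl at 1.38-fold, Cps1 at 1.38-fold and Gnmt at 1.34-fold. Among 14 pericentral hepatocyte markers Cyp1a2 and Oat fell and Cldn2 rose 1.46-fold (5 lower and 1 higher when adjusted over the list alone). These lists shifted down (adjusted p = 0.0221, 0.0131 and 0.0291), but not with an estimated correlation (adjusted p = 0.419, 0.419 and 0.493) or with reference centring (adjusted p = 0.299, 0.193 and 0.213, each the highest over the alternatives, the lowest being 0.000929, 0.000977 and 0.000973). Their medians of -0.41, -0.13 and -0.21 did not shrink there, but were -0.59, -0.31 and -0.39, or unchanged relative to all genes (-0.39, -0.11 and -0.19), and 7, 12 and 4 members were called lower. Among 11 periportal markers Ctsc, which encodes a lysosomal protease also abundant in leukocytes, rose 2.59-fold and Cyp2f2 fell (1 and 1 when adjusted over the list alone), with no shift (adjusted p = 0.282).

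Of 15 male-biased, growth hormone-dependent genes, 5 fell (8 lower and 1 higher when adjusted over the list alone), among them Elovl3, Slco1a1, Hsd3b5 (2.53-fold) and Keg1 (1.57-fold). The list shifted down (camera adjusted p = 4.23e-06, and adjusted p = 0.255 with an estimated correlation). Of 10 female-biased genes 0 passed in limma (0 when adjusted over the list alone, 2 higher and 1 lower at an unadjusted p below 0.05), with Cyp17a1 at 0.88 and Acot3 at 0.33 (adjusted p = 0.996 for the list). In the circadian clock list the repressor gene Nr1d1 fell 1.57-fold as the only call among 18 (7 lower and 1 higher when adjusted over the list alone). That list shifted down (adjusted p = 0.0143, and adjusted p = 0.255 with an estimated correlation), though not with reference centring (adjusted p = 0.247, with a range from 0.00229 over the alternatives). There the median was -0.47 instead of -0.29, or -0.27 relative to all genes in both cases, and 6 members were called lower.

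In the unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, 7 of 20 genes rose and 1 fell (12 higher and 3 lower when adjusted over the list alone). Ddit3 rose 2.49-fold, Sdf2l1 2.07-fold and the disulfide isomerase gene Pdia4 1.69-fold, whereas Trib3, a target of the same stress pathway, fell 2.57-fold. As a whole it shifted up (camera adjusted p = 1.12e-06, and adjusted p = 0.255 with an estimated correlation). Among 14 genes of metal and iron handling, Mt1, Mt2 and the transferrin receptor gene Tfrc (2.90-fold) rose, and Ireb2 fell 1.47-fold (4 higher and 1 lower when adjusted over the list alone). This list shifted up (adjusted p = 0.0131, and adjusted p = 0.255 with an estimated correlation), with a median of 0.16, or -0.01 with reference centring, which was 0.18 relative to all genes in both cases, with the list called in both. The calls of Mt1, Tfrc and, in the unfolded protein response, Ddit3 depended on how probe sets were handled. Chosen after their values were seen, the remaining calls of lists with 5 calls were Cyp2c23 (-0.70) among phase I enzymes, Il18bp (0.74) among cytokines, Cd68 (0.78) among macrophage markers, Hgd (-0.42) in amino acid catabolism and Cyp2u1 (-0.52) among male-biased genes.

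**Figure D4:**
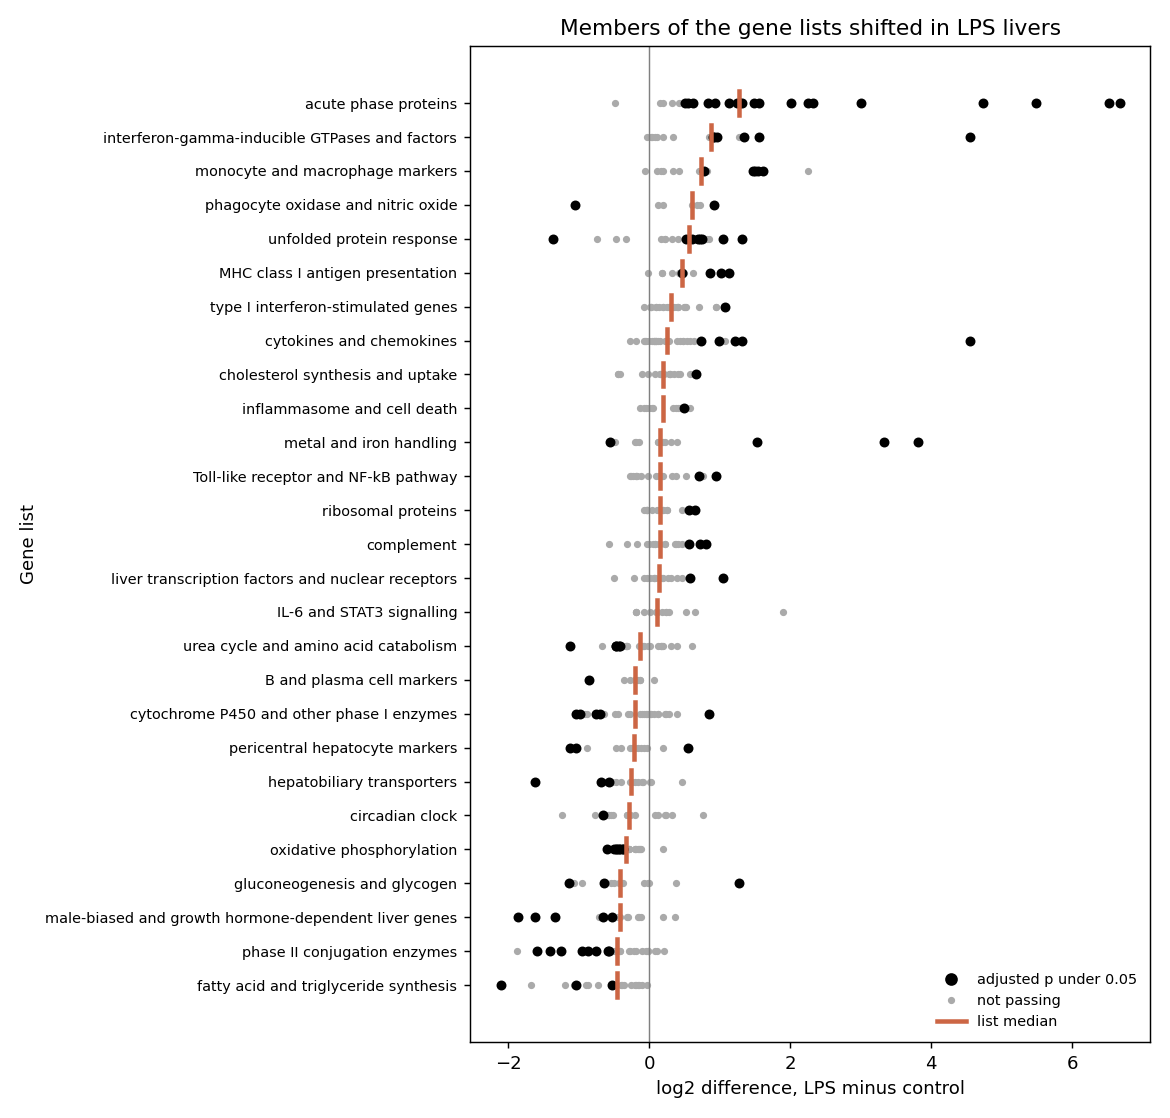
Difference in log2 signal (LPS minus control) of each measured member of the 27 lists shifted by camera with the preset correlation, with 1 dot per gene, black for genes with an adjusted p below 0.05, and a bar at the list median. Medians run from -0.46 for fatty acid and triglyceride synthesis to 1.27 for acute phase proteins, and with the arrays centred on reference genes, which lowers every gene by the same amount, 6 of the positive medians turn negative while their lists stay called up.

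With camera's preset correlation 16 lists shifted up, 11 shifted down and 22 did not shift. With an estimated correlation camera called 0 lists (5 at an unadjusted p below 0.05, lowest adjusted p = 0.255), and fry called 5 up, endothelial activation among them, and 6 down. Of the 27 shifts, 14 held in every alternative with the preset correlation, and 8 of the others were lost without at least 1 array. Cholesterol synthesis was lost without control replicate 3 (adjusted p = 0.134) or LPS replicate 2 (0.0587), the clock without LPS replicate 3 (0.0567), and metal handling without control replicate 1 (0.0863). IL-6 signalling was lost without control replicate 1 (0.0912) or LPS replicate 4 (0.0547), the Toll-like receptor list without control replicate 3 (0.0979) or LPS replicate 3 (0.0519), and the urea cycle without control replicate 3 (0.172). Glucose metabolism was lost without control replicate 2 (0.0671), control replicate 3 (0.086), LPS replicate 3 (0.103) or LPS replicate 4 (0.0547). Pericentral markers were lost without control replicate 1 (0.205), LPS replicate 1 (0.0629), LPS replicate 3 (0.0785) or LPS replicate 4 (0.105).

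Other settings ended list calls as well. Limiting the test to genes above the dim level ended those of the Toll-like receptor (adjusted p = 0.332), inflammasome (0.169), clock (0.107), IL-6 (0.0903), pericentral (0.0649) and glucose (0.0537) lists, and limiting it to the 9096 brighter genes also that of the phagocyte oxidase list (0.0701). Without probe sets that can match several transcripts the ribosomal protein (0.343), phase I (0.111), metal (0.104) and urea cycle (0.0749) lists were not called. With the mean of all probe sets the IL-6 (0.0956) and B and plasma cell (0.0787) lists were not called. The beta-actin covariate ended the calls of the glucose (0.155), pericentral (0.0865), clock (0.0682), urea cycle (0.0567), phase I (0.0544) and Toll-like receptor (0.0534) lists.

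Centring each array on 11 reference genes, of which Tfrc was itself called higher, moved the median difference of all genes from -0.02 to -0.20. The reference genes had a mean difference of 0.18 and a median of 0.08, with Tfrc at 1.54, so most of this move came from Tfrc. It gave 246 genes higher and 1633 lower, so that 13.1% of calls were higher instead of 52.0%.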

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

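The tests of a wrong label, of a swap and of a mixed sample, and the test of Kupffer cell number, were chosen after the results were seen. A wrong label and a mixed sample were each tested again after the first test was read, and the bound of the first wrong-label test was changed after its value was seen. An earlier test of Kupffer cell number, the count of markers that passed as higher, was dropped because the pattern itself fixed its outcome, and another was put in its place.

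LPS replicate 5 stood apart from the other 4 LPS mice on the first principal component, where its gap to the nearest of them was 0.776 of the range. Among 137 named genes, 28 had 1 LPS mouse far from the other 4 by Dixon's ratio (critical value 0.71), and in 24 of these it was LPS replicate 5. Chance flags about 1 in 20 groups. The gap of LPS replicate 5 in log2 units was 2.66 for S100a9, 2.496 for Cxcl9, 2.183 for Lcn2, 2.151 for Serpina3n, 1.879 for Orm2, 1.418 for Gbp6, 0.956 for Ccl6, 0.946 for Saa2, 0.944 for Ccl7, 0.861 for Saa3, 0.41 for Serping1 and 0.391 for Saa1, all with this mouse lowest. It was highest, by 2.023 for Mme, 1.667 for Clec4f, 1.597 for Me1, 1.456 for Acot1, 1.263 for Gsta4, 0.87 for Gstm3, 0.755 for Cyp2f2, 0.595 for Hsd3b5, 0.556 for Cyp2c55, 0.188 for Cd5l, 0.103 for Alb and 0.067 for Serpinc1. LPS replicate 3 lay lowest by 1.156 for Cyp17a1, 0.242 for Klf1 and 0.209 for Cela1, and LPS replicate 4 by 0.524 for H2-Aa. Over all genes LPS replicate 3 was apart more often (2.83% of genes) than LPS replicate 5 (1.83%).

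A control liver under a wrong label is argued against by the 25 acute phase genes, over which LPS replicate 5 lay a median of 0.422 log2 units above the controls, where the highest control lay 0.109 above the other controls, and by Saa3, at 13.3 against at most 7.48 in controls. The earlier test of this was the share of genes called higher without this mouse in which it lay above all 3 controls (51.509%, 25% by chance). It was first read as excluding a wrong label. Control replicate 2, however, lay above the other 2 controls in 56.2% of its own set of 600 genes, so with the bound changed the test was left undecided. These shares are not alike, since chance puts an array above 2 others more often than above 3, and the genes differ. A swap with a control mouse is argued against by the control arrays, none of which lay further than 0.088 of the way to the other LPS mice, and degraded RNA by the beta-actin 3' to 5' signal difference (2.007 log2 units), within the range of the other arrays. A mixture of LPS and control liver RNA stays open: a single LPS share of 0.23 misfitted 2.796% of called genes, below the 3.5% of LPS replicate 3, the array with the highest 3' to 5' difference, but above the 0, 1.02 and 0.893% of LPS replicates 1, 2 and 4, and in the later test 8.756% of genes at least 2-fold apart were misfitted, against 3.39% for LPS replicate 3 (Fisher's exact test, two-sided p = 0.266, across genes, which are not independent) and 0 of 39, 41 and 39 for the others, whose fits, unlike its own, took LPS replicate 5 into the spread. No biological explanation, such as a weaker response of this mouse, was tested, because the labels give no group for it.

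Kupffer cell markers moved apart, with Clec4f and Fcna lower and Marco and Cd5l higher. A loss of Kupffer cells alone, as the reason for the fall of Clec4f (-1.97), would lower the other markers about as much. Without Clec4f and Marco the median of the other 11 was -0.078, with an SD of 0.691 between them. As Clec4f was picked for its large fall, the other markers were likely to lie above it. The values therefore argue only against a loss as large as that fall, and say nothing about a smaller loss of these cells. A change of expression within these cells, and fewer resident cells beside recruited macrophages that share some of the markers, stay open, since bulk liver RNA does not separate them and neither was tested.

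Outside the genes compared above, 17 probe sets with no gene symbol and 15 with several symbols were higher in LPS than in controls, and 19 and 3 were lower.

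All 56 splits of the 8 arrays into 5 and 3 were fitted. As many genes higher were found in the real split alone (1 of 56, 271 genes, highest other 106), and likewise as many at least 2-fold higher (1 of 56, 81 genes, highest other 37). Chance is thus excluded at 0.05 for each of these numbers on its own. There was no adjustment over the numbers tested, and with 56 splits this test can give no p below 0.0179. As many genes lower were found in 2 splits (250, highest other 359) and as many at least 2-fold lower in 2 (28, highest other 59). Each share, taken on its own, is also below 0.05, but another split gave more calls. In both cases the other split set LPS replicates 1, 2 and 4 against the controls and LPS replicates 3 and 5, so the treatment itself can give such numbers there. For lists shifted up, 3 splits gave as many (16, highest other 17), and for lists shifted down 10 splits did (11, highest other 17), so chance is not excluded for the numbers of lists. The other 2 splits for lists up each exchanged a control for LPS replicate 5, which lay near the controls, and 4 of the others for lists down set 3 of LPS replicates 1 to 4 against the rest, so these splits carry part of the treatment difference too.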

How the results depend on the processing

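All alternatives were planned except the beta-actin covariate, which was chosen after seeing the data. Among the 101 called named genes no other direction was reversed than that of Rps9, which was -0.0966 without probe sets of the suffixes _s_at, _x_at and _a_at, since another probe set then stood for the gene. All 101 named calls were kept with array weights, with repeated quantile normalization and without LPS replicate 5, 100 with the replicate block, 95 with reference centring, 84 with median centring, 63 with the covariate, 62 with trend and robust eBayes and 55 with the mean of probe sets. With single arrays other than LPS replicate 5 left out, 8 (control replicate 1) to 49 (LPS replicate 3) were kept. Of 92 named calls above the dim level, 92 were kept, and of 87 left without the suffixes, 72.

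The numbers higher, lower, at least 2-fold higher and at least 2-fold lower were 271, 250, 81 and 28. They were 26, 11, 19 and 3 at an adjusted p below 0.01, 891, 805, 136 and 55 with array weights, and 117, 146, 48 and 12 with the mean of probe sets. With trend and robust eBayes 36 and 6 were at least 2-fold higher and lower. Genes lower numbered 162 with median centring, 1633 with reference centring (66 at least 2-fold) and 155 with the beta-actin covariate (14 at least 2-fold), and 166 genes were higher without the suffixes. Lists shifted down numbered 7 above the dim level, 7 among the brighter genes, 6 with reference centring and 6 with the covariate. Lists shifted up and down numbered 0 and 0 with an estimated correlation, and 5 and 6 with fry. Each array left out in turn gave 11 to 928 genes higher, 2 to 753 lower, 11 to 149 at least 2-fold higher and 1 to 68 at least 2-fold lower, 14 to 18 lists up and 8 to 12 lists down. The filters tested fewer genes, and leaving out an array left fewer samples. The replicate block took LPS replicates 4 and 5 out of the difference. For the other settings the cause was not tested.

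The labels state no pairing by replicate number, and deviations of same-numbered arrays correlated across genes at -0.005, 0.263 and -0.052. With 3 controls such correlations cannot tell whether the numbers mark a shared day or batch. LPS replicates 4 and 5 had no control of the same number, so the replicate block took them out of the difference. It thus compared LPS replicates 1 to 3 with controls 1 to 3, and blocking cannot be told apart from leaving out those 2 mice. With the replicate block 759 genes were higher and 589 lower, 160 and 70 at least 2-fold, and 20 lists shifted up and 12 down. In that setting S100a9 moved from 2.82 to 3.44 and Ubd from 2.42 to 3.06 log2 units, and no other called named gene by over 1.5 times. Not every array correlated best with the array of its own number. Signals near the background of the array limit low genes such as Il6 (3.07 in LPS), since 9161 of 18193 genes exceeded 6.48, the 95th percentile of 75 receptor genes of the senses.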

Other observations

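The list tests and the test of food intake were planned, and the values of single arrays given last were noted after the data were seen.

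Vascular and matrix genes gave calls without a list shift in the main test. Among 19 matrix and stellate cell genes, Vim (2.70-fold) and Col4a1 (2.25-fold) rose, as did Timp1 (0.39 log2 units), chosen after its value was seen, and Reln (2.41-fold) and Ecm1 (1.68-fold), which stellate cells express, fell (3 higher and 3 lower when adjusted over the list alone). The list had a median of -0.11, a mean of 0.02 and no shift (adjusted p = 0.988). Cd44 rose by 0.94 log2 units and was with Lcn2 the only call among 10 genes of endothelial activation (3 when adjusted over the list alone). That list had a median of -0.01, a mean of 0.82, raised mostly by Lcn2 (6.52), and no shift in the main test (camera adjusted p = 0.0673). It was called in 7 of 19 alternatives (lowest camera adjusted p = 0.00205, up with reference centring) and by fry (up, adjusted p = 0.0243). Of 17 sinusoidal endothelial markers 0 passed in limma (3 higher and 1 lower when adjusted over the list alone, 6 higher and 3 lower at an unadjusted p below 0.05), with Fcgr2b at 0.52 and Clec4g at -0.20 (adjusted p = 0.148 for the list). Fcgr2b passed without LPS replicate 5 (limma adjusted p = 0.00616, with a range from there to 0.857 over the alternatives). Casp4, a sensor of LPS inside cells, rose from 5.09 to 5.59, both close to background, as the only call among 12 inflammasome and cell death genes (1 when adjusted over the list alone), a list that shifted up (adjusted p = 0.00886, and adjusted p = 0.289 with an estimated correlation), but not among genes above the dim level (adjusted p = 0.169, the highest over the alternatives, the lowest being 0.000912). Among 17 liver transcription factors and nuclear receptors Esr1 (2.06-fold) and Prox1 (1.49-fold) rose (2 when adjusted over the list alone), and Hnf4a differed by 0.07. That list shifted up (adjusted p = 0.0134, and adjusted p = 0.289 with an estimated correlation), with a median of 0.14, or -0.04 with the arrays centred on reference genes, which was 0.16 relative to all genes in both cases, with the list called in both.

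The ribosomal protein genes Rps20 (1.57-fold) and Rps9 (1.48-fold) rose among 18 (3 when adjusted over the list alone), but without probe sets that can match several transcripts Rps20 differed by 0.02 and Rps9 by -0.0966, and the list was not called (adjusted p = 0.343, the highest over the alternatives, the lowest being 1.22e-05). With all probe sets the list shifted up (adjusted p = 6.27e-05, and adjusted p = 0.419 with an estimated correlation), with a median of 0.16, or -0.02 with reference centring, which was 0.18 relative to all genes in both cases, with the list called in both. In limma 0 genes passed in the lists for cell cycle (Pcna -0.17, Ccnd1 0.19), growth arrest (Ccng1 0.21, Trp53inp1 0.23), oxidative stress (Gpx1 -0.16, Cat -0.09) and proteasome (Psma3 -0.16, Psma4 -0.01). The same held for cholangiocytes (Epcam 0.11, Sox9 0.13), dendritic cells (Batf3 -0.20, Flt3 -0.02) and erythroid cells (Alas2 -0.43, Klf1 -0.09), with both group means of Sox9 and Flt3 below 6.48, close to background. Alas2 came close (limma adjusted p = 0.0506) and passed in 7 of 18 alternatives, among them the fit without LPS replicate 5 (adjusted p = 0.0393). At an unadjusted p below 0.05 these lists held 5, 2, 3, 2, 1, 0 and 1 genes, and adjusted over the list alone 0, 2, 1, 1, 0, 0 and 1. None of them shifted (adjusted p from 0.163 to 0.988). Medians and tests differed in sign for dendritic cells (-0.02, up) and cholangiocytes (0.03, down), and means and tests for oxidative stress (0.02, down) and female-biased genes (0.06, down). The pancreatic protease gene Cela1 fell 1.41-fold as the only call among 7 pancreas and adipose markers (1 when adjusted over the list alone, list adjusted p = 0.138), and the 11 reference genes, with Tfrc as the only call (1 higher and 1 lower when adjusted over the list alone), did not shift (adjusted p = 0.137).

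Lower signals of lipogenic genes such as Me1 and Elovl3 could come from lower food intake after LPS. In 12 genes that rise in the fasted liver, written down before the test, the median difference was -0.0172, with 0 higher and 0 lower in limma. Without LPS replicate 5 it was -0.0944, with 0 higher and 2 lower (Cpt1a and Angptl4, chosen after their values were seen). A median near 0 over members that went both ways decides nothing, so food intake and a direct effect of LPS cannot be told apart for these genes.

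Control replicate 2 had the highest signal of the controls in 16 of 25 acute phase genes, with Saa2 at 11.02 and Orm2 at 8.82, while control replicate 3 had the highest Mt1 and Mt2. In the comparison of LPS replicate 5 with a mixture, Saa3 lay 1.14 log2 units above and S100a9 1.26 below what a single share gave.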
